A study of Mus musculus with 10 samples.

How the data were processed

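Colon RNA of 10 wild-type mouse samples was sequenced, 5 labelled as normal diet and 5 as pro-inflammatory diet. Per the labels' protocols, total RNA was checked for integrity, and libraries were made with a stranded mRNA kit and sequenced in pairs on an Illumina instrument. The deposited table holds 1 FPKM value (mapped fragments scaled to gene length and to the library's total) per gene symbol and sample, for 18398 genes, as the authors made it. The submitters' processing notes name Trimmomatic, HISAT2, Bowtie2, HTSeq, Cufflinks, StringTie and DESeq with the mm10 genome, without saying which step each served. Whether counting used the strand is not given in the sources used here, so overlapping and antisense genes, near-identical gene copies such as the haemoglobin genes, and gene families are uncertain. FPKM divides by gene length and by each library's total, so a few very abundant genes in a library lower the values of all its others. The total FPKM per library ran from 380001 to 404462. Mitochondrially encoded genes and immunoglobulin constant genes were not analysed here. The labels do not say that the samples came from separate animals, or whether colitis was induced in any of them. The p-values therefore measure only the spread between these samples, which may be technical in part. Samples were grouped by the treatment label and are named here by group and the number in their title.

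The values of each gene were whole multiples of what 1 read is worth, within 0.001 read, for 18398 of 18398 genes. This gave 15652783 to 18341956 reads on genes per library, and the length of each gene relative to the others. On simulated data, 100% of 701 genes with 50 or more reads were recovered exactly. In a chi-square comparison of these reads, the closest pair of libraries differed by 11.51 per gene, far above sampling noise, so no library was counted as a copy of another. Between 1179 and 2041 genes were listed at 0 per library. Gene symbols were matched to the GENCODE M21 annotation of GRCm38, the same assembly as mm10, for 17740 genes, and to RefSeq GRCm38.p6 for 18283. Coordinates are from GENCODE M21, 1-based. Of 124 symbols starting with LOC, 84 were absent from that RefSeq release, so the gene models of the deposited table came from another release.

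The 12345 genes with a mean FPKM of at least 1 over all samples were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using eBayes with a mean trend, and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are on this scale, pro-inflammatory minus normal diet, and understate the change of low genes. For each of 50 gene lists fixed before the data were examined, members with a value were counted, and the 45 lists with at least 4 tested members were tested with limma's camera at its preset correlation of 0.01. Camera with a correlation estimated from the data and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it. The mean log2 value of each list per library was compared with a two-sided exact permutation test over the 252 splits of 10 libraries into 5 and 5, whose smallest p is 0.00794. Principal components used the tested genes. In simulated data with the means and spreads of these 12345 genes in 5 against 5 libraries, 58.2% of genes changed by 1.5-fold were called, 92.5% of those changed by 2-fold and 98.5% of those changed by 4-fold, with 9 false calls. These simulations drew each gene on its own, without the correlation between genes of the real libraries. They changed 67, 67 and 66 genes at these folds. The Benjamini-Hochberg cut-off depends on how many genes change, so these shares need not hold for the real data.

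The genes named were chosen by a rule fixed in advance. It takes up to 12 genes per direction that pass the threshold without overlap between groups, filled up to 10 with the smallest unadjusted p where fewer qualify; 4 members with the smallest p from each list that camera calls; at most 2 from other lists; and Il1b, Il6, Tnf, Lcn2, Muc2, Tjp1, Ocln and Cldn1 whatever their p. Some genes that the rule takes are not reported here. Genes named to describe single libraries were chosen after their values were seen. Other settings chosen before the data were examined changed the pseudocount (0.1 and 0.5), the filter on low values, the scaling, the variance model, the sample weights, the test, the threshold and the gene set, added a replicate block or a tissue make-up covariate (smooth muscle minus epithelial list score), and left out each library in turn. Further settings were added after the data were seen. They left out libraries that stand apart, added covariates for distal colon genes and clock genes, removed trends with gene length or GC content, or ran limma voom on the whole reads. Figures were drawn with matplotlib 3.10.9.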

Results

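The colon transcriptome was compared between 5 samples from mice on a normal diet and 5 from mice on a diet described as pro-inflammatory. The series' title refers to colitis and gut microbiota, and the comparison asks which genes of the colon differ between the diets. Each library held between 15652783 and 18341956 reads on genes. Pearson correlations between libraries, over log2(FPKM + 1) of 12345 genes, ran from 0.911 to 0.992.

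The list of nuclear-encoded genes of mitochondrial respiration was called higher on the pro-inflammatory diet and that of smooth muscle lower, by camera at its preset correlation. Neither was called with an estimated correlation (adjusted p = 0.557 and 0.584), fry gave adjusted p values of 0.0422 and 0.107, and no single gene passed the adjusted threshold. The gene with the smallest p was Creb3l2, a transcription factor of the secretory pathway (chromosome 6, 37327255 to 37442146, minus strand, GRCm38), at 10.4 ± 0.963 FPKM on the normal and 6.54 ± 0.57 on the pro-inflammatory diet (SD, n = 5 each; log2 fold change -0.60, SE 0.08, limma adjusted p = 0.147). Also lower without passing were Rims1, Lpp, Crybg3, Bclaf1, Syne2, Tead1 and Map3k20, with log2 fold changes of -0.71, -0.44, -0.33, -0.27, -0.31, -0.36 and -0.32. Npas2, a clock transcription factor (chromosome 1, 39193731 to 39363236), was at 9.64 ± 2.85 against 3.79 ± 0.832 FPKM. Npas2 was at 10.3 to 13.1 in normal diet libraries 1, 2 and 3, which stood apart in clock genes, and at 6.54 and 6.87 in libraries 4 and 5, and its log2 fold change went from -1.13 to -0.703 without these 3. Slc34a2, a phosphate transporter (chromosome 5, 53038081 to 53071664), was at 18.4 ± 3.37 against 8.13 ± 2.59 FPKM. Among genes with higher values, Fancl, a ubiquitin ligase of DNA crosslink repair (chromosome 11, 26386135 to 26471876), was at 3.73 ± 0.399 against 5.62 ± 0.285 FPKM (log2 fold change 0.49, SE 0.07, adjusted p = 0.151). Slc30a10, a manganese exporter (chromosome 1, 185454848 to 185468762), was at 1.13 ± 0.307 against 3.86 ± 1.67 FPKM. Ndufs8 of respiratory complex I, the mitochondrial fission gene Fis1, Calml4, the glycolytic gene Pfkl, Lsm4, Sephs2, Qdpr and Idh1 had log2 fold changes of 0.33, 0.27, 0.31, 0.39, 0.28, 0.50, 0.25 and 0.46. None of these passed either (adjusted p = 0.151). In limma, 0 of 12345 genes passed in either direction, 1007 were higher and 1142 lower at an unadjusted p under 0.05, and voom on the whole reads also called 0. The 5 values of one diet all lay above the 5 of the other for 218 genes higher and 255 lower on the pro-inflammatory diet, 3.83% of those tested where chance gives 0.794%.

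Oxidative phosphorylation genes, which encode subunits of the respiratory chain and ATP synthase, were higher in 53 of 55 measured members. Ndufs8 was at 66.9 ± 0.977 FPKM on the normal and 84.7 ± 5.43 on the pro-inflammatory diet, Sdhb of complex II at 131 ± 6.01 against 165 ± 13.4, Cyc1 of complex III at 136 ± 6.75 against 164 ± 7.97, and Uqcrq of complex III at 74.4 ± 4.81 against 93.2 ± 7.26. Over all genes 0 members passed, while 29 passed adjusted over the list alone, all higher. Camera called the list higher (median log2 fold change 0.15, adjusted p = 3.96e-19), but not with an estimated correlation (adjusted p = 0.557). Fry gave an adjusted p of 0.0422. The list score was higher in each pro-inflammatory diet library than in every normal diet library (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.179 over 45 lists). The tight and adherens junction score, lower on that diet, also did not overlap between the diets (same exact permutation p and adjusted p). Shorter genes had higher fold changes across genes, which are not independent replicates (Spearman's rho = -0.268 between length and log2 fold change), and the median length of these members was 0.303 of the median of all tested genes.

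**Figure D1:**
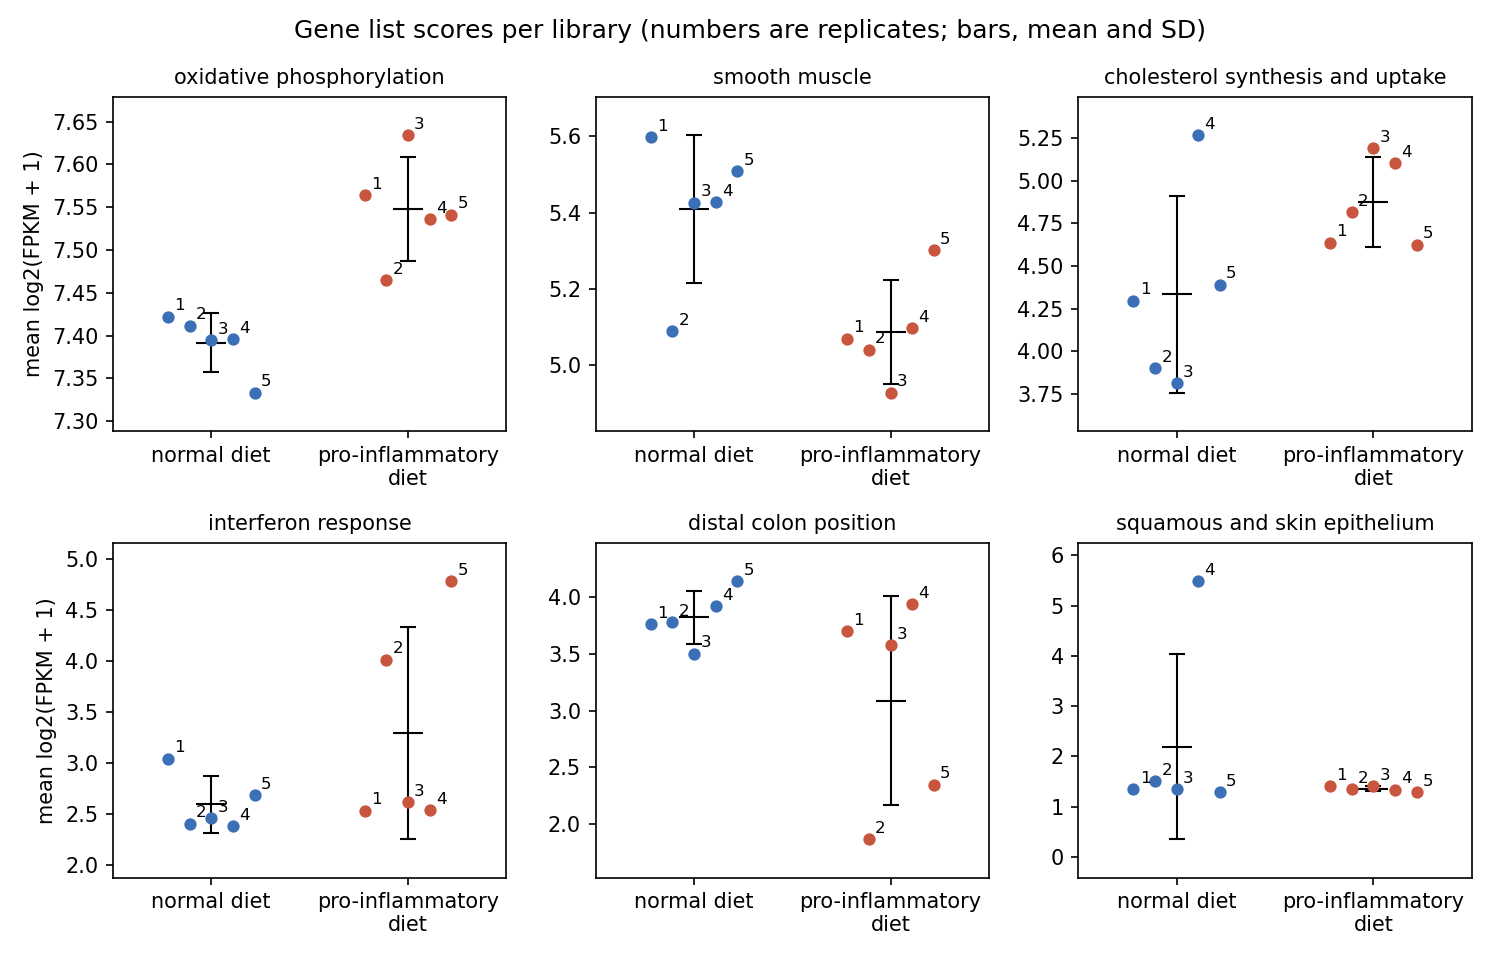
Mean log2(FPKM + 1) of the members of 6 gene lists (vertical axes, not starting at 0) in each library of the 2 diets, with the replicate number beside each point and bars for the mean and SD. The oxidative phosphorylation scores do not overlap, while the interferon and distal colon scores of pro-inflammatory diet libraries 2 and 5, and the squamous score of normal diet library 4, lie apart from the rest.

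Carbohydrate and lipid metabolism lists were also called higher. The glucose and sugar metabolism list had 15 of 24 members higher, with 3 passing adjusted over the list alone (camera adjusted p = 0.00676; adjusted p = 0.584 with an estimated correlation). Pfkl, a phosphofructokinase (chromosome 10, 77986947 to 78010083), was at 34.6 ± 2.7 against 45.8 ± 3.14 FPKM, and Fbp2 and Pklr had log2 fold changes of 0.27 and 0.29. Fatty acid oxidation and PPAR target genes were higher in 31 of 36 members, 0 passing adjusted over the list alone (camera adjusted p = 5.7e-07; adjusted p = 0.584 with an estimated correlation), with Eci1 at 0.25, Acaa1b at 1.73, Acadvl at 0.26 and Ehhadh at 0.39. The score of this list, a mean log2(FPKM + 1), was 4.87 and 4.96 in pro-inflammatory diet libraries 2 and 5, against 4.11 to 4.51 in the other 3 on that diet and 4.04 to 4.33 on the normal diet. Without these 2 libraries the list stayed called (adjusted p = 0.0344), while its score difference went from 0.347 (SE 0.167) to 0.107 (SE 0.107). The call ended with distal colon and clock scores together as covariates (adjusted p = 0.675, median 0.055 against 0.255). Cholesterol synthesis and uptake genes were higher in 24 of 26 members, 0 passing adjusted over the list alone (median log2 fold change 0.59, camera adjusted p = 5.7e-07; adjusted p = 0.584 with an estimated correlation). Fdps, an enzyme of the mevalonate pathway, was at 43.9 ± 27.8 against 72.5 ± 14.7 FPKM, and Nsdhl, Mvk and Lss had log2 fold changes of 0.69, 0.78 and 0.93. Normal diet libraries 1, 2 and 3, where the clock output gene Dbp was at 1.79 to 6.69 FPKM against 12.4 to 54.3 in the other 7, had the 3 lowest cholesterol list scores. Without these 3 libraries the cholesterol call ended (adjusted p = 0.674, median -0.014 against 0.590), as did the glucose call (adjusted p = 0.661, median -0.001 against 0.169). That fit kept 2 normal diet libraries, 4 and 5. Library 4 had the highest score of all 10 for cholesterol (5.27) and for glucose (5.52). Library 5 lay below every pro-inflammatory diet library in both lists (4.39 against 4.63 to 5.19, and 5.165 against 5.177 to 5.374). Without pro-inflammatory diet libraries 1 and 3 the glucose list had an adjusted p of 0.0767, with a median about as large (0.152). The clock covariate alone also ended the glucose call (adjusted p = 0.588, median 0.016). With both covariates the adjusted p was 0.123 for cholesterol (median 0.175) and 0.215 for glucose (median 0.092).

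Genes of detoxification and redox defence formed another higher group. The xenobiotic and aryl hydrocarbon receptor list was higher in 30 of 36 members, 1 passing adjusted over the list alone (camera adjusted p = 0.000349; adjusted p = 0.557 with an estimated correlation). Ces2c, a carboxylesterase, was at 76.9 ± 5.3 against 109 ± 17.2 FPKM, and Gsto1 and Ugt1a7c had log2 fold changes of 0.28 and 0.30, while Tiparp, a target of the aryl hydrocarbon receptor, was at -0.18. The xenobiotic score was 5.20 and 5.22 in pro-inflammatory diet libraries 2 and 5, against 4.55 to 4.56 in the other 3 and 4.33 to 4.57 on the normal diet. Without them the list stayed called (adjusted p = 0.00172), with a score difference of 0.136 (SE 0.064) against 0.398 (SE 0.167) over all 5. The antioxidant list was higher in 20 of 22 members, 0 passing adjusted over the list alone (camera adjusted p = 0.00048; adjusted p = 0.557 with an estimated correlation). Its log2 fold changes were 0.25 for Gclm, 0.23 for Prdx1, 0.23 for Ftl1 and 0.19 for Cat. With distal colon and clock covariates together its adjusted p was 0.0703, with a median of 0.110 against 0.136.

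Smooth muscle and extracellular matrix lists were called lower. In the smooth muscle list 24 of 25 members were lower, 12 of them passing adjusted over the list alone (median log2 fold change -0.34, camera adjusted p = 4.15e-08; adjusted p = 0.584 with an estimated correlation). The myosin light chain Myl9 was at 518 ± 56.1 against 399 ± 52.2 FPKM, Tpm1 at 206 ± 18.7 against 166 ± 15.4, Pgm5 at 38.3 ± 6.55 against 26.5 ± 3.83 and the muscle regulator Myocd at 2.54 ± 0.478 against 1.63 ± 0.244. Extracellular matrix genes were lower in 33 of 39 members, 0 passing adjusted over the list alone (camera adjusted p = 2.74e-05; adjusted p = 0.584 with an estimated correlation), with log2 fold changes of -0.40 for Col5a2, -0.37 for Col12a1, -0.39 for Lum and -0.68 for Eln. The epithelial identity list was called higher in 16 of 21 members (camera adjusted p = 0.0441; adjusted p = 0.584 with an estimated correlation), with 0.48 for Phgr1, 0.23 for Cdh17, 0.25 for Krt8 and 0.16 for St14. That call ended without normal diet library 1, 4 or 5, or pro-inflammatory diet library 3, 4 or 5 (adjusted p from 0.0596 to 0.171, medians from 0.070 to 0.124 against 0.110), and with quantile normalization (adjusted p = 0.723, median 0.020). With the smooth muscle minus epithelial score as a covariate, which holds the muscle list itself, the matrix call ended (adjusted p = 0.213, median -0.043 against -0.218).

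Of the immune gene lists, 7 were called higher, and in 6 of them pro-inflammatory diet libraries 2 and 5 had the highest scores. The B cell score was instead highest in library 1 of that diet (3.03, with 2.51 and 2.13 in libraries 2 and 5 and 1.51 to 2.36 on the normal diet). Library 1 also lay close to library 5 for MHC class II (5.0012 and 5.0555) and dendritic cells (2.22 and 2.24). Interferon response genes, induced by type I and II interferons, were higher in 41 of 41 members, 0 passing adjusted over the list alone (median log2 fold change 0.61, camera adjusted p = 8.85e-08; adjusted p = 0.584 with an estimated correlation). Oas1a was at 20.6 ± 2.53 against 36.6 ± 21 FPKM and Bst2 at 16.1 ± 1.16 against 32.7 ± 21.5, while Epsti1 and Ifih1 had log2 fold changes of 0.42 and 0.40. The other calls were MHC class I presentation (15 of 15 higher, adjusted p = 4.96e-05; Psmb10 0.43, Psmb9 0.75, Erap1 0.17, Tap1 0.79), T cells and natural killer cells (10 of 10, adjusted p = 0.000136; Cd2 0.67, Cd3g 0.84, Lck 0.53, Cd4 0.43) and macrophages and monocytes (20 of 21, adjusted p = 0.00261; Ly6c2 0.65, Aif1 0.53, Plac8 0.52, Tyrobp 0.32). MHC class II presentation (10 of 11, adjusted p = 0.00282; H2-Oa 0.59, H2-Aa 0.51, H2-Eb1 0.48, H2-Ab1 0.51), B cells (16 of 16, adjusted p = 0.00449; Cd180 0.54, Fcrla 0.53, Bank1 0.29, Cd79b 0.40) and dendritic cells (8 of 10, adjusted p = 0.0167; Irf8 0.46, Itgae 0.39, Itgax 0.33) were also called higher. With an estimated correlation, these 7 lists gave adjusted p values of 0.584, or 0.668 for B cells. Of all their members, only H2-Oa passed adjusted over its list alone. Without libraries 2 and 5, only the B cell list of the 7 stayed called (adjusted p = 0.0341, median 0.289 against 0.279), and the interferon list had an adjusted p of 0.874 in the lower direction. With array weights, 6 of the 7 calls ended, all but interferon (adjusted p from 0.0503 to 0.208). The dendritic cell call also ended without normal diet library 4, or without pro-inflammatory diet library 1 or 2 (adjusted p = 0.0818, 0.0583 and 0.101, medians 0.253, 0.304 and 0.200 against 0.323). The B cell call ended without normal diet library 4 or pro-inflammatory diet library 1 (adjusted p = 0.0975 and 0.16, medians 0.151 and 0.107).

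The cell proliferation list, of replication and mitosis genes, was higher in 36 of 37 members, 0 passing adjusted over the list alone (camera adjusted p = 2.58e-06; adjusted p = 0.584 with an estimated correlation). Tk1 was at 7.08 ± 1.74 against 14 ± 6.41 FPKM, and Ccne1, Mcm5 and Mcm7 had log2 fold changes of 0.72, 0.81 and 0.64. This call also ended without libraries 2 and 5 (adjusted p = 0.874). The adipocyte list was called higher (14 of 15 members, adjusted p = 0.0231; adjusted p = 0.679 with an estimated correlation), with Pparg at 0.59, Fabp4 at 0.80, Cyp2e1 at 1.58 and Acvr1c at -0.32, and this call ended without any 1 of 4 libraries, normal diet library 5 or pro-inflammatory diet library 1, 2 or 5 (adjusted p from 0.101 to 0.193, medians from 0.239 to 0.462 against 0.597). The haemoglobin genes of the red blood cell list were higher in 4 of 4 members, 3 passing adjusted over the list alone (camera adjusted p = 0.00452; adjusted p = 0.584 with an estimated correlation). The list score was 3.73, 3.62 and 3.87 in pro-inflammatory diet libraries 1, 3 and 5. In libraries 2 and 4 of that diet it was 2.22 and 2.37, inside the normal diet range of 1.97 to 2.51. Hbb-bs was at 13.6 ± 1.61 against 36.8 ± 18.1 FPKM, and Hba-a2, Hbb-bt and Hba-a1 had log2 fold changes of 0.88, 1.02 and 0.64. These near-identical genes can share reads, and the call ended without pro-inflammatory diet libraries 1 and 3 (adjusted p = 0.076, median 0.635 against 0.951), with the clock covariate (adjusted p = 0.0829, median 0.706) and with both covariates (adjusted p = 0.254, median 0.614).

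Barrier genes and the usual readouts of colitis did not pass singly. In the tight and adherens junction list 19 of 25 members were lower, 0 passing adjusted over the list alone (camera adjusted p = 0.0231; adjusted p = 0.557 with an estimated correlation). Cldn8, a sealing claudin (chromosome 16, 88560828 to 88563183), was at 54.3 ± 8.81 against 23.2 ± 13.3 FPKM, Ocln at 37.2 ± 2.29 against 29.8 ± 5.79 and Tjp1 at 29.9 ± 1.17 against 25.2 ± 3.8, while the pore-forming Cldn2 was at 60.3 ± 6.97 against 76 ± 8.78. Without pro-inflammatory diet libraries 2 and 5, the log2 fold changes of Cldn8, Ocln and Tjp1 went from -1.405, -0.327 and -0.249 to -0.740, -0.126 and -0.113. Without normal diet library 2 or 4, or pro-inflammatory diet library 1, the adjusted p was 0.073, 0.0818 and 0.0716, while the median stayed at -0.117, -0.144 and -0.161 against -0.151. With a distal colon score as covariate the call ended (adjusted p = 0.0852) and the median was -0.075. It also ended with the length trend removed (adjusted p = 0.0585, median -0.093) and without pro-inflammatory diet libraries 1 and 3 (adjusted p = 0.0594, median -0.200). Its score was 5.16 and 5.17 in pro-inflammatory diet libraries 2 and 5, 5.28 to 5.29 in the other 3 and 5.37 to 5.45 on the normal diet, and without these 2 libraries the list stayed called (adjusted p = 0.0416) with a median of -0.079. Il1b was at 0.839 ± 0.186 against 1.49 ± 0.585 FPKM (log2 fold change 0.41, adjusted p = 0.222), Lcn2 at 5.25 ± 2.78 against 4.11 ± 0.375, the mucin Muc2 at 657 ± 294 against 914 ± 731 and Cldn1 at 1.85 ± 1.57 against 1.08 ± 0.593, with adjusted p values of 0.618, 0.862 and 0.54. Normal diet library 4 held Lcn2 at 10.2 and Cldn1 at 4.58 FPKM, and without it their log2 fold changes went from -0.205 to 0.027 and from -0.361 to -0.085. The direction of Muc2 turned with the setting: its log2 fold change was 0.193 over all libraries, -0.665 without pro-inflammatory diet libraries 2 and 5, and -0.931 with the distal colon covariate and without normal diet library 4, where it passed (adjusted p = 0.0346). With the clock covariate it was 0.995 (adjusted p = 0.402). Il6 (0.0309 ± 0.0284 against 0.0926 ± 0.0469 FPKM) and Tnf (0.591 ± 0.135 against 0.878 ± 0.557) lay under the minimum and were not tested. The lists of acute inflammation and antimicrobial defence (adjusted p = 0.403), inflammatory cytokines and chemokines (0.127), type 3 lymphoid response (0.656) and goblet cells and mucus (0.835) were not called. The acute inflammation score was 6.56 and 6.60 in pro-inflammatory diet libraries 2 and 5, against 4.64 to 5.75 in the rest. The cytokine and chemokine list was called higher with a clock covariate (camera adjusted p = 0.0354, median 0.293 against 0.175). The goblet cell list was called lower with the distal colon covariate (adjusted p = 0.0163) or without normal diet library 4 and pro-inflammatory diet libraries 2 and 5 (adjusted p = 0.00711), but higher with a clock covariate (adjusted p = 0.00398) or without normal diet libraries 1, 2 and 3 (adjusted p = 0.00175).

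Single libraries stood apart within both groups. Component 1, with 50.4% of the variance, set pro-inflammatory diet libraries 2 and 5 (scores 52.65 and 46.24) apart from the other 8 (-16.57 to -4.19), and component 2, with 17.9%, set apart normal diet library 4 (-40.34). Neither differed between diets (exact permutation p = 0.349 and 0.937). Component 3, with 10.6%, looked at after the data were seen, separated the diets without overlap (exact permutation p = 0.00794, adjusted p = 0.0317 over 4 components). In libraries 2 and 5 of the pro-inflammatory diet, Hoxb13, a gene of the most distal colon (chromosome 11, 96194316 to 96197447), was at 0.417 and 20.9 FPKM against 211 to 341 in the other 8, and Osr2 was at 66.1 and 49 against at most 3.58. The list of distal colon position was called lower (8 of 9 members, adjusted p = 0.0126; adjusted p = 0.584 with an estimated correlation), with Hoxd12 at -0.65, Hoxd13 at -1.91 and Hoxa10 at -0.28. Without these 2 libraries that call ended (adjusted p = 0.541) and the median went from -0.545 to -0.119. Without normal diet library 4 the adjusted p was 0.0525 while the median stayed at -0.503. The squamous and skin epithelium list was called lower (18 of 18 members, adjusted p = 0.0162; adjusted p = 0.689 with an estimated correlation), with Sfn at -0.55, Sprr2a3 at -0.39, Dmkn at -0.93 and Krt5 at -1.18. Normal diet library 4 had Krt5 at 50.2 FPKM against at most 0.116 in the other 9, and without it the call ended (adjusted p = 0.738, median -0.064 against -0.830). Without pro-inflammatory diet library 1 the adjusted p was 0.0568, with a median of -0.839.

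**Figure D2:**
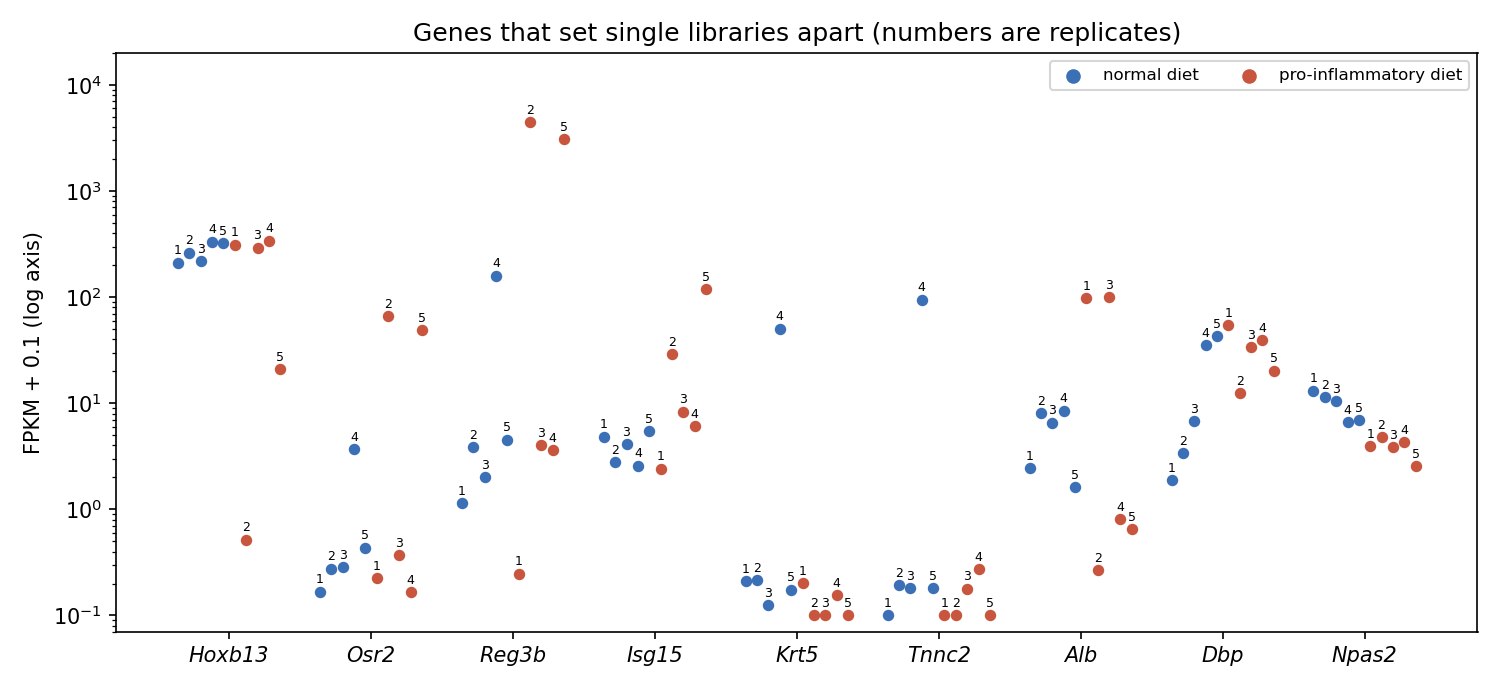
FPKM + 0.1 (log axis) of 9 genes in each library, with the diet as colour and the replicate number above each point. Pro-inflammatory diet libraries 2 and 5 lie apart for Hoxb13, Osr2 and Reg3b, normal diet library 4 for Krt5 and Tnnc2, and pro-inflammatory diet libraries 1 and 3 for Alb.

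Over all lists, camera called 17 higher and 5 lower of 45 at the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.557), and fry called 1. Leaving out normal diet library 4 with pro-inflammatory diet libraries 2 and 5 left 9 of the 22 calls in place. These were oxidative phosphorylation, cholesterol, glucose, fatty acid oxidation, xenobiotic, antioxidant, red blood cell, smooth muscle and extracellular matrix genes. The pro-inflammatory diet libraries left were 1, 3 and 4, and libraries 1 and 3 held RNA of liver genes (Alb at 97.3 and 100 FPKM). Library 4 scored above every remaining normal diet library for oxidative phosphorylation, cholesterol, glucose and antioxidant genes. For the other lists that stayed called, it lay within the range of those normal diet libraries.

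**Figure D3:**
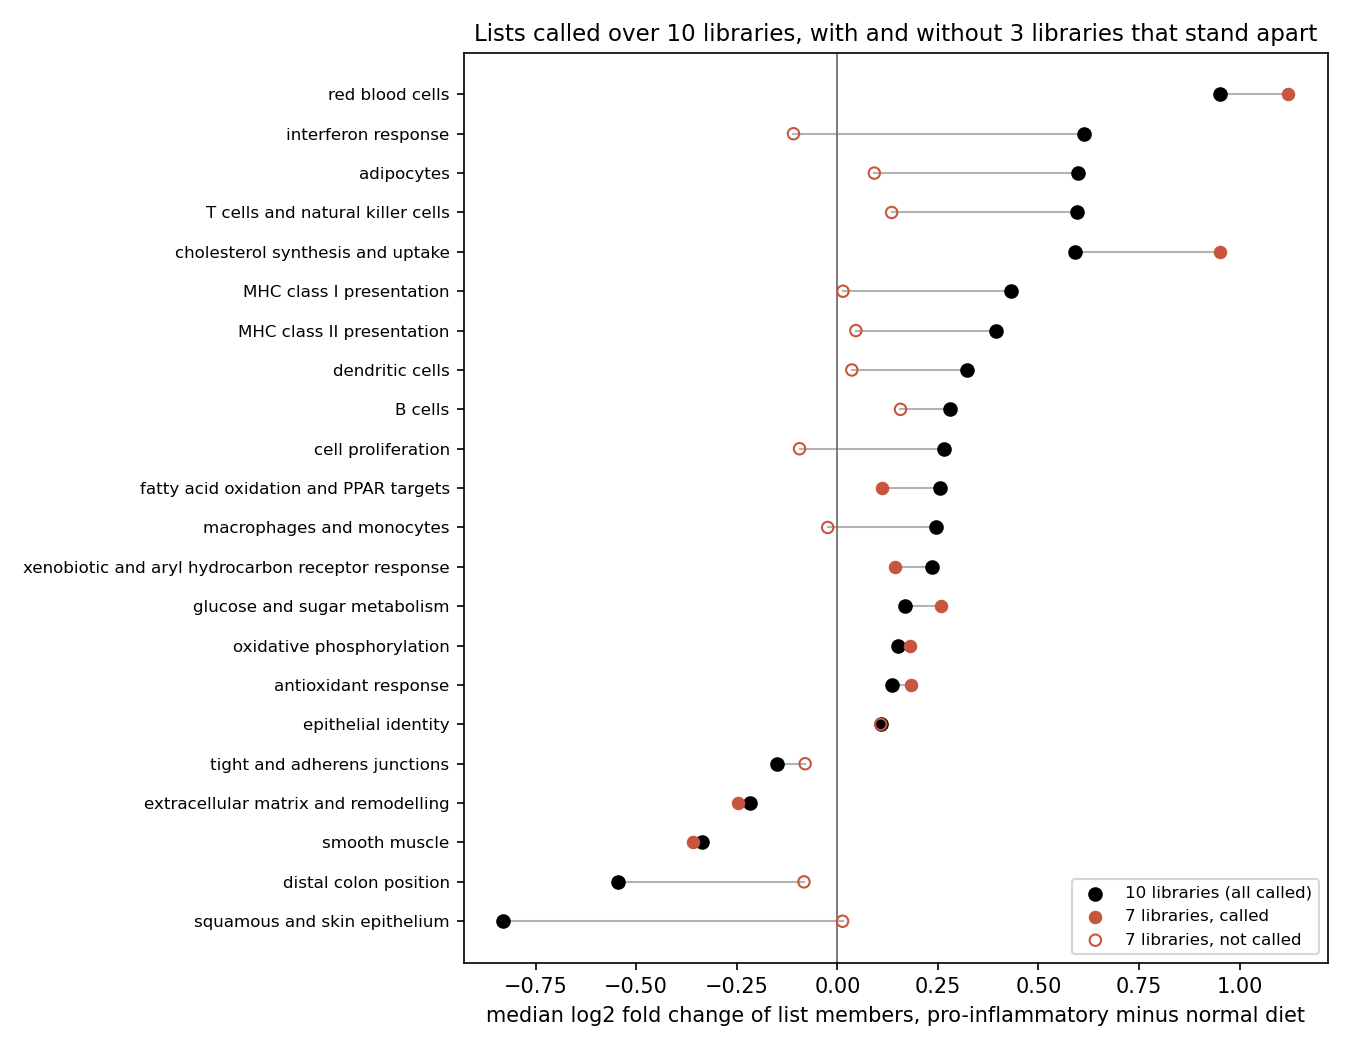
Median log2 fold change of the members of the 22 called lists (horizontal axis), over all 10 libraries (black) and over 7 libraries without normal diet library 4 and pro-inflammatory diet libraries 2 and 5 (red, filled where still called). The interferon median moves from 0.61 to -0.11, while oxidative phosphorylation and smooth muscle stay near 0.18 and -0.36.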

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

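The tests of the 2 libraries, of the shared response, of the clock, of ribosomal protein genes and of splits for genes at an adjusted p were chosen after the results they bear on were seen, while those of the length trend, of smooth muscle and of the other splits were written first. In 150 comparisons of a single library with the other 4 of its group, 12 stood apart, where chance gives about 1 in 20, or 7.5. This was Dixon's test (95% critical value 0.71 for 5 samples), which can miss 2 libraries of a group that lie apart together. Pro-inflammatory diet libraries 2 and 5, at 52.65 and 46.24 on component 1, were such a pair.

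Normal diet library 4 accounted for 10 of these 12 comparisons. Its mean log2 score was 5.74 for the skeletal muscle list against 0.802 to 0.926 in the other 4, 5.48 for squamous and skin epithelium against 1.29 to 1.51, and 4.97 for small intestine against 2.04 to 2.19. It was 3.7 for chylomicron and dietary lipid handling, 4.98 for bile acid sensing and transport, 5.52 for glucose and sugar metabolism and 6.15 for the antioxidant response, above 2.94, 4.15, 5.17 and 5.98 in the others. Its component 2 score was -40.3. Lcn2 was at 10.2 FPKM there against 3.63 to 4.72, and Cldn1 at 4.58 against 0.905 to 1.84. The remaining 2 were Sephs2 at 23 FPKM in normal diet library 2, against 29.3 to 31, and Qdpr at 55.7 FPKM in pro-inflammatory diet library 1, against 58.7 to 59.8.

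Of 7 immune lists called higher, the first pattern weighed, 1 (B cells) stayed called without pro-inflammatory diet libraries 2 and 5, which were low in Hoxb13 and high in Osr2. The interferon score of the other 3 libraries on the diet differed from the normal diet by -0.031 (SE 0.167), against 0.701 (SE 0.481) over all 5, which argues against an interferon response shared by all mice on the diet. MHC class I and T cells, 2 of the other 5 lists that ended, also fell. MHC class I went from 0.472 (SE 0.282) to 0.044 (SE 0.113), which argues against a shared response of that list. T cells went from 0.662 (SE 0.33) to 0.165 (SE 0.136), which argues against it only weakly. Library 1 of the diet had a T cell score of 1.59, above the normal diet range of 0.987 to 1.25. B cells stayed at 0.293 (SE 0.342) through library 1 (score 3.03), with libraries 3 and 4 (2.07 and 1.84) inside the normal diet range of 1.51 to 2.36 and a difference of -0.066 (SE 0.275) without library 1, so these errors leave a shared response open for B cells, as for MHC class II, macrophages and dendritic cells. A candidate explanation is tissue from a more proximal part of the colon in these 2 libraries, while a response to the diet in these 2 samples alone was not tested and stays open.

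The cholesterol list was the second. With a clock score as covariate (evening minus morning clock genes), its score difference went from 0.54 (SE 0.283) to 0.213 (SE 0.303), and without normal diet libraries 1, 2 and 3 it was 0.046 (SE 0.303). Without pro-inflammatory diet libraries 2 and 5 it was 0.643 (SE 0.366), which argues against a proximal origin of these libraries as the cause. Collection at different clock phases may therefore account for some of it, although camera still called the list with the clock covariate. Without normal diet libraries 1, 2 and 3, only libraries 4 and 5 stand for that diet. Library 4, which also held RNA of skin and skeletal muscle genes, had the highest cholesterol score of all 10 (5.27). Library 5, at a clock score of 2.39, scored 4.39, below every pro-inflammatory diet library (4.63 to 5.19). How much the clock accounts for cannot be told from these values. The lowest clock scores lie in normal diet libraries 1, 2 and 3 (-0.371 to 0.365). Pro-inflammatory diet library 2 came next at 1.17, and the rest ran from 2.32 to 2.83. The clock score thus largely follows the diet labels and the standard errors are wide. An effect of the diet on cholesterol genes or on the clock therefore stays open.

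For the third, the oxidative phosphorylation list, a length trend was removed per library, after which its score difference went from 0.157 (SE 0.031) to 0.092 (SE 0.018) and camera still called it (adjusted p = 2.59e-08), so length was not the whole cause. It lay above the bound of 0.078 set in advance by less than its SE, and a part may come from length. With the smooth muscle minus epithelial score as covariate it was 0.148 (SE 0.049), which argues against a smaller share of muscle. Ribosomal protein genes, also short, differed by -0.029 (SE 0.094), but by 0.113 (SE 0.043) without pro-inflammatory diet libraries 2 and 5, where oxidative phosphorylation differed by 0.187 (SE 0.03). An effect of RNA quality on short transcripts and an effect of the diet therefore cannot be told apart here.

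For single genes there was no call to weigh against chance, since the diet split gave 0 and 100 of 100 splits of the 10 libraries gave at least as many, with 476 the highest of the others. For the 2149 genes at an unadjusted p under 0.05, 3 of 100 splits gave as many, the real one included. The highest other count was 3062. So high a count was thus uncommon among the splits. Splits that mix the diets gave more, so the count does not tell a diet effect from another structure of the samples. For the 22 lists called by camera at its preset correlation, 30 of 100 splits called as many, with 26 the highest other, so chance was not excluded. The split with 476 and 3062 genes exchanged normal diet library 4 and pro-inflammatory diet library 1. The other split with many genes, 182 at an adjusted and 2219 at an unadjusted p, set normal diet libraries 1, 2 and 3 with pro-inflammatory diet libraries 2 and 5 against the rest. These libraries had the lowest clock scores (-0.371 to 2.32, against 2.33 to 2.83 in the rest), and libraries 2 and 5 were also those low in Hoxb13. An exchange of labels was not tested as such. On component 3, normal diet library 4 was at 12.9 and the others on its diet at 3.82 to 11.79, and pro-inflammatory diet library 1 was at -14.48 where its diet ran from -21.79 to -0.43. The oxidative phosphorylation score was 7.40 in normal diet library 4 (7.33 to 7.42 on its diet) and 7.56 in pro-inflammatory diet library 1 (7.46 to 7.63). Both measures, picked after the data were seen, separated the diets without overlap, so every library had to lie with its own label. They therefore cannot weigh an exchange. Normal diet library 4 correlated at 0.967 and 0.965 with pro-inflammatory diet libraries 4 and 3, against 0.956 to 0.961 with its own diet. With pro-inflammatory diet libraries 1, 2 and 5 its correlation was 0.959, 0.911 and 0.923. Pro-inflammatory diet library 1 correlated best with library 3 of its diet (0.987), then with normal diet library 5 (0.986). The counts of 476 and 182 against 0 for the diet split point to a structure of the samples, and its source was not tested.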

How the results depend on the processing

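The alternatives that left out named libraries together, added distal colon or clock covariates, removed length or GC trends or used voom were chosen after seeing the data. No gene passed the adjusted threshold in any alternative except 1 higher (Kyat1) with the distal position covariate and 156 higher and 114 lower with that covariate without normal diet library 4. A common cut-off of unadjusted p 0.05 with a fold of at least 2 gave 12 higher and 12 lower. At an unadjusted p under 0.05, where the main counts were 1007 higher and 1142 lower, 658 were higher in the exact Wilcoxon test, 663 higher and 661 lower with the tissue make-up covariate, 221 and 280 without the 3 libraries of another clock phase (2 against 5 libraries remain), and 490 and 348 with both covariates. With Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Jchain left out and each library rescaled to the same total FPKM, 647 were higher and 1671 lower. That is 27.9% higher against 46.9%, and the median log2 fold change shifted by -0.033. Leaving out these genes and rescaling were not run apart. Leaving out 1 library gave 649 to 1207 higher, lowest without normal diet library 2, and 810 to 1482 lower. The cause of these changes was not tested. The replicate numbers did not pair the samples: same-numbered deviations correlated between -0.263 and 0.061 and no library correlated best with its own number. With the replicate block, 0 genes passed, 873 were higher and 963 lower at an unadjusted p, and 19 lists were called higher and 6 lower, with 22 of 22 calls kept.

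The main test called 17 lists higher and 5 lower. Counts for each setting below hold all lists called there, also ones not called in the main test. There were 9 higher with a mean FPKM of at least 5 (fewer genes tested) and 10 higher and 3 lower with array weights. An estimated correlation gave 0 and 0, and fry 1 and 0. With array weights, 11 main calls were kept and 11 lost. Excluding the 2 libraries low in distal colon genes gave 9 higher, excluding normal diet library 4 gave 2 lower, excluding these 3 gave 9 higher, and excluding the 3 of another clock phase gave 9 lower. The distal covariate gave 8 higher, 11 without library 4, the clock covariate 9 lower, and both covariates 3 higher and 9 lower. With both covariates, 5 main calls were kept and 17 lost. Leaving out 1 library gave 14 to 19 higher and 2 to 6 lower, lowest without normal diet library 4 (2) and pro-inflammatory diet library 1 (3). The direction turned for interferon (adjusted p = 0.874 without the 2 libraries, 0.6 without the 3, 0.0282 with both covariates), proliferation (0.874 and 0.233), adipocytes (0.966 without the 2 libraries, 0.889 with the distal covariate, 0.546 with both), and with both covariates for MHC class I (0.524), macrophages (0.321), dendritic cells (0.779) and T cells (0.81), and for epithelial identity with the tissue make-up covariate (0.267). The oxidative phosphorylation call was lost with an estimated correlation (0.557) and in no other of 35 alternatives. At 15652783 to 18341956 reads per library, genes under 1 FPKM on average were not tested.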

Other observations

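The genes of single libraries and the covariate fits given here were chosen after the data were seen, while the lists were fixed before. RNA of liver genes was present in some libraries: albumin (Alb) was at 97.3 and 100 FPKM in pro-inflammatory diet libraries 1 and 3 against at most 8.45 in the other 8, and the urinary protein gene Mup3 was at 51.5 and 40.7 against at most 2.1. Normal diet library 4 held RNA of skeletal muscle genes (Tnnc2 at 94.5 FPKM against at most 0.174 elsewhere), skin genes (Krt1 at 85.1 against at most 0.0782) and the Paneth cell defensin Defa24 (117 against at most 2.85). The antimicrobial lectin Reg3b was at 4429 and 3064 FPKM in pro-inflammatory diet libraries 2 and 5, at 159 in normal diet library 4 and at most 4.44 in the other 7. The Y-linked gene Ddx3y was at 11.5 to 17.5 FPKM in all 10 libraries.

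Most other cell types and pathways were not called by camera. For epithelial lineages, adjusted p was 0.919 for colonocyte transport (Car1, 324 ± 124 against 1555 ± 1356 FPKM, SD, n = 5), 0.514 for stem cell and Wnt targets (Ephb3, log2 fold change -0.49), 0.328 for enteroendocrine cells (Tac1 -0.30, Pyy -0.52) and 0.526 for tuft cells (Cd24a 0.35). Tuft cells were called lower with the distal colon covariate (adjusted p = 0.0272, median -0.252 against 0.038) or without normal diet library 4 and pro-inflammatory diet libraries 2 and 5 (0.0188, median -0.300), but higher with the clock covariate (0.0128, median 0.293). Enteroendocrine cells were called lower with the distal colon covariate (0.00946, median -0.223 against -0.128) and without the same 3 libraries (0.0459, median -0.216). For stroma it was 0.186 for enteric neurons and glia, 0.79 for endothelium (Lyve1 -0.41) and 0.38 for fibroblasts (Grem1 -0.60, Ly6a 0.62), with 1 endothelial and 2 fibroblast members lower adjusted over the list alone. Plasma cells gave 0.0519 (Txndc5 0.40, Jchain 0.57). Lipid and bile lists gave 0.127 for fatty acid synthesis (Slc25a1 0.42), 0.127 for chylomicron handling (Sar1b 0.18) and 0.0519 for bile acid sensing (Abcc3 0.43). Endoplasmic reticulum stress gave 0.919, immediate early genes 0.259, the circadian clock 0.58 (2 members lower adjusted over the list alone), ribosomal proteins 0.596 and histone genes 0.189 (H1f2 -0.91). Skeletal muscle gave 0.0832, small intestine 0.756 and pancreatic acinar genes 0.259. Of the 23 lists not called, 7 were called when 1 library was left out. Enteric neurons and glia were lower without pro-inflammatory diet library 2 or 5 (adjusted p = 0.0262 and 0.0123), and lower without both (adjusted p = 8.38e-05, median -0.419 against -0.141 over all 10). Skeletal muscle was lower without normal diet library 1, 2, 3 or 5 (0.0204 to 0.0332). Plasma cells were higher without normal diet library 2 or 3 or pro-inflammatory diet library 3 or 4 (0.00787 to 0.0303), and bile acid sensing without normal diet library 5 or pro-inflammatory diet library 3 or 4 (0.0128 to 0.044). Bile acid sensing was instead called lower with distal colon and clock covariates together (adjusted p = 0.0079, median -0.163 against 0.540). Its score was 6.29 and 5.91 in pro-inflammatory diet libraries 2 and 5 against 3.87 to 4.98 in the other 8, and without these 2 the median was 0.044 (adjusted p = 0.607). Fatty acid synthesis was higher without normal diet library 4 (0.00366), and chylomicron handling without that library or pro-inflammatory diet library 3 (0.0492 each). Ribosomal proteins were higher without pro-inflammatory diet library 2 (0.0191) and lower without library 3 of that diet (0.0301). The goblet and endoplasmic reticulum stress lists had medians below 0 while camera pointed higher. Neutrophil, mast cell and eosinophil lists had 2, 3 and 1 tested members and were not tested as lists; Lrg1 among them had a log2 fold change of 0.51 (adjusted p = 0.197).

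With distal colon genes as a covariate, 1 gene passed, Kyat1, named after its values were seen (log2 fold change 1.02, SE 0.09; 0.12 without the covariate). With this covariate and without normal diet library 4, 156 genes were higher and 114 lower, among them Pfkl, Creb3l2, Npas2 and Mvk, and Muc2 lower (log2 fold change -0.931, adjusted p = 0.0346). The clock genes Ciart and Per2 also passed there (1.91 and 1.08). With distal colon and clock covariates together over all 10 libraries, 0 genes passed in limma (smallest adjusted p = 0.473; 490 higher and 348 lower at an unadjusted p under 0.05). Normal diet library 4 was part of that fit, and with it the distal colon covariate alone already gave only 1 gene. The loss of calls therefore cannot be put down to the clock covariate. Whether the genes that passed without library 4 follow the diet or the clock phase of normal diet libraries 1, 2 and 3 stays open.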
